A study of Mus musculus with 5 samples.

How the data were processed

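Single cells of kidney and small intestine were profiled in 5 libraries of male mice aged 8 to 10 weeks, 1 library per group, on the BD Rhapsody system. Per the labels, the kidney libraries hold innate lymphoid cells and the intestinal libraries group 3 innate lymphoid cells (ILC3s), in both cases sorted. UUO is the ligation of a ureter, and in sham surgery the ureter was exposed only. The labels also describe a digestion of pulmonary artery tissue, which does not match the organs named, and it is not settled here which protocol was used. The groups were wild-type kidney 3 and 14 days after UUO, kidney labelled PD-1 knockout 3 days after UUO, and wild-type intestine after sham surgery or 3 days after UUO. The number of mice per library is not given in the sources used here.

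The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell, with 31253 genes, of which 31107 had their identifier in the GRCm38 gene table. The submitters' processing notes name CASAVA 1.8, UMI-tools, Seurat and the mm10 genome; the aligner, the annotation and the rule for calling cells are not given in the sources used here. Counts of wild-type kidney at day 3 were not used here, and for that library only its 5444 barcodes were counted. Counts of wild-type kidney at day 14 carried no gene names of their own and took those of the 3 other libraries, whose gene lists were identical. This was checked by the correlation across genes of log2(CPM + 1) with the knockout-labelled kidney, 0.992, which dropped to 0.21 with the genes shifted by 1 place. With sham and UUO intestine it was 0.931 and 0.918.

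Total depth was 10362652 UMIs in 5282 barcodes for wild-type kidney at day 14, 16466027 in 7007 for the knockout-labelled kidney, 8717372 in 3621 for sham intestine and 14756545 in 5209 for UUO intestine. The smallest cells held 394, 501, 501 and 501 UMIs, so shallower barcodes had been removed before. Cells were kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs, which retained 98.7, 99.3, 96.7 and 95.0% of barcodes. Median mitochondrial shares of the kept cells were 4.75, 5.43, 3.22 and 3.92%.

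The kept cells of the 4 libraries were clustered together without batch integration. Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes seen in at least 20 cells were chosen, leaving out immunoglobulin and T cell receptor segments, mitochondrial and ribosomal protein genes. Clusters came from 30 principal components, 15 neighbours and the Leiden algorithm at resolution 1.0 with seed 1. Markers of 17 cell types, fixed before the data were examined, named the clusters. A marker counted when its CPM + 10 was at least 2 times that of all other cells and it had a UMI in at least 10% of the cells of the cluster. A cluster took the name with the most markers, at least 3, unless its 10 leading genes were cell cycle genes or held more markers of another class, and gamma-delta markers counted as T cell markers. This way of counting markers was settled after the first clustering had been seen. As intestinal ILC3-like cells made up much of all other cells, the bar for ILC3 markers in a small kidney cluster was high, and cells without a class name are reported as a share.

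UMI counts were summed per library and class and divided by the class total (CPM). Levels carry exact Poisson 95% intervals, shares exact binomial intervals, and log2 ratios exact conditional binomial (Clopper-Pearson) intervals, all covering counting error only. A zero count took CPM + 1 on both sides, and a share of 0 was set against a floor of 3 counts. Classes with at least 100 cells in both libraries were compared: intestinal ILC3-like cells after UUO against sham, and kidney ILC2-like and ILC1/NK-like cells of the knockout-labelled library against wild-type kidney at day 14. The same comparison of T-like clusters 0, 3 and 7, of epithelium-like cells and of single ILC3-like clusters was added after the data were seen. Kidney and intestine were set side by side over all kept cells. For shares of cells with a UMI, each cell was thinned to 1000 UMIs and shallower cells were left out. With 1 library per group, no test was made and no p-value given.

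The genes named were fixed by a rule before the data were examined: in each comparison the 10 highest and 10 lowest ratios among genes with at least 100 UMIs in both libraries together and at least 50 CPM in the higher, of which at least the first 6 are named. Mitochondrial, ribosomal protein, predicted, immunoglobulin, T cell receptor segment, sex-linked and haemoglobin genes were left out. Up to 4 members of each list with the largest ratio could be named, and Pdcd1, Cxcr6, Ccr9, Il17a, Il22 and Il23r always were. The 21 gene lists, also fixed before, were PD-1 axis and inhibitory receptors, ILC3 identity and regulators, ILC3 cytokines and effectors, LTi/CCR6 subset, NCR+/type 1 ILC3 subset, migration and homing receptors, IL-17 and JAK-STAT signalling, NF-kB and TNF response, dissociation and immediate early, heat shock, interferon response, MHC class II, MHC class I, cell cycle, glycolysis, oxidative phosphorylation, lipid metabolism, circadian clock, apoptosis and survival, glucocorticoid response, and TGF-beta response and fibrosis-linked. Members with at least 20 UMIs counted as measured, and a list needed 3. The median log2 ratio of a list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Its percentile describes these libraries and is not a test, and a list is called outside the central range below the 2.5 or above the 97.5 percentile. Members are described as at least 1.5 times higher, at least 1.5 times lower or in between. The marker lists of the 17 cell types were measured in the same way.

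The intervals and list percentiles were tested on simulated data with 200 changed genes and 100 simulations of unchanged lists per comparison. The true ratio lay inside the interval for 93.4, 95.1 and 94.3% of genes in intestinal ILC3-like, kidney ILC2-like and kidney ILC1/NK-like cells. Changes of 1.5-fold were placed on the right side of 0 in 88.1, 82.1 and 95.5% and changes of 2-fold in 98.5, 97.0 and 98.5% of simulated genes. Lists with no changed gene fell outside the central range in 3.76, 5.95 and 5.33% of simulations. Simulated UMIs were drawn independently, so coverage near 95% follows from the design and checks the computation only. Simulated libraries differ by counting alone, so a difference between mice or preparations is not covered. UMIs bunched in few cells are not covered either.

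Alternatives tried were 2 cell filters (any barcode with a UMI; 1000 UMIs, 500 genes and 10% mitochondrial UMIs), Leiden resolutions of 0.5 and 2.0, each library clustered alone, totals without mitochondrial and ribosomal protein genes, edgeR TMM factors, all kept cells in place of a class, cells thinned to 1000 or 2000 UMIs, other minimums for lists (100 UMIs; 1 UMI in each library) and for named genes (20 and 200 CPM). Doublets were scored with Scrublet at an expected rate of 0.06. Its own threshold called 7 of 20619 cells, so its planned removal could not be used, and the 6% of cells with the highest scores in each library were removed instead. That setting, single clusters, cells without a CD3 UMI and cells without barcodes shared by the intestinal libraries were chosen after the data were seen. Left out were the counts of wild-type kidney at day 3, and contrasts of kidney ILC3-like cells, of which there were 2 and 0.

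Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, scanpy 1.11.5 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.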

Results

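Cell counts of 4 libraries were compared: kidney of wild-type mice 14 days after unilateral ureteral obstruction (UUO), kidney labelled PD-1 knockout 3 days after UUO, and small intestine of wild-type mice after sham surgery or 3 days after UUO. Each group is 1 library, so there are no replicates and no difference was tested. Ranges in brackets are exact 95% intervals covering counting error only. The libraries kept 5212, 6960, 3501 and 4946 cells in that order. Their medians were 1824, 2064.5, 2039 and 2177 UMIs and 1060, 1150, 1188 and 1240 genes per cell. Expression is given as CPM, the UMIs of a gene scaled by the total of the summed cells. Ratios are given as log2. The highest and lowest ratios of a comparison are those among genes with at least 100 UMIs in both libraries together and 50 CPM in the higher, which leaves out weaker genes with larger ratios.

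Pdcd1, which encodes the inhibitory receptor PD-1 (chromosome 1, 94038305 to 94052553, minus strand), was counted in every library, including the library labelled PD-1 knockout. Over all kept cells it stood at 127 (119.9 to 134) CPM in wild-type kidney at day 14 and 189.6 (183 to 196) CPM in the library labelled PD-1 knockout. In the intestine it was 50.5 (45.7 to 55.5) CPM in sham intestine and 46.9 (43.4 to 50.7) CPM in UUO intestine. The counted 3' tag may lie outside the deleted part of the gene, which the labels do not give. These levels check neither the genotype nor the label. The share of cells with a Pdcd1 UMI, with the share after thinning every cell to 1000 UMIs in brackets, was 16.4% (10.6%, 9.72 to 11.5%) in wild-type kidney and 28.4% (17.2%, 16.3 to 18.1%) in the knockout-labelled kidney. It was 8.57% (4.73%, 4.03 to 5.52%) in sham intestine and 9.18% (5.26%, 4.62 to 5.97%) in UUO intestine. Thinning left out 361, 376, 269 and 577 shallower cells. In intestinal ILC3-like cells the shares were 9.11% (4.98%, 4.23 to 5.83%) in sham and 9.99% (5.79%, 5.07 to 6.58%) after UUO. Here 117 and 300 cells were left out, at median depths of 2039.5 and 2174 UMIs. Intestinal epithelium-like cells, which should lack the gene, held 6.19% (2.46%, 0.510 to 7.02%) and 6.31% (1.15%, 0.314 to 2.92%), a measure of the background. Their median depths were 1631 and 3108 UMIs. Within the ILC3-like cells Pdcd1 lay mostly in cluster 1, the cluster with Tnfsf11 (RANK ligand) among its leading genes. The shares there were 16.1% (8.57%, 7.17 to 10.1%) in sham and 16.9% (8.85%, 7.62 to 10.2%) after UUO. Cluster 2, led by Csf2 and the gut-homing receptor Ccr9, held 2.35% (1.01%, 0.463 to 1.91%) and 2.83% (1.55%, 0.924 to 2.45%), close to the epithelial background after thinning.

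T cell-like cells made up most of the kidney libraries, although the labels describe sorted innate lymphoid cells. They were 66.8% (65.5 to 68.0%) of kept cells in wild-type kidney at day 14 and 63.3% (62.1 to 64.4%) in the knockout-labelled kidney at day 3. These shares include cluster 8, with 403 and 293 cells, which carried Cd3d, Cd3e and Trdc. Its leading genes hold the Ly49 receptor genes Klra1, Klra6, Klra7 and Klra9, of which the last 2 also lead ILC1/NK-like cluster 9. With each library clustered alone, wild-type kidney had 60.1% T-like and 24.3% ILC1/NK-like cells. ILC1/NK-like cells, marked by Xcl1 and Ncr1, and in cluster 9 also by Klra8, were 18.2% (17.2 to 19.3%) and 19.8% (18.9 to 20.7%). ILC2-like cells, marked by Il1rl1, Il5 and Calca, were 9.96% (9.16 to 10.8%) and 11.1% (10.4 to 11.9%). Cycling cluster 18, led by Pclaf, Top2a and Mki67, also carried ILC2 markers but got no class name, and its 24 wild-type and 72 knockout-labelled kidney cells are not in these shares. ILC3-like cells numbered 2 in wild-type kidney, 0.0384% (0.00465 to 0.139%), and 0 in the knockout-labelled kidney, where a count of 3 would be 0.0431%. These counts depend on the marker bar. Cluster 17, with 43 wild-type and 103 knockout-labelled kidney cells, reached fewer than 3 markers of any class at that bar and got no name. It was led by MHC class II genes, with Cd74 at 3883 (3509 to 4287) CPM in wild-type and 6025 (5747 to 6312) CPM in knockout-labelled cells and H2-Aa at 3261 (2918 to 3632) and 4144 (3914 to 4383). At lower levels it held genes of several classes. In the same order it had Kit at 415 (299 to 561) and 228 (177 to 289.9) CPM, Tmem176a at 1077 (884 to 1299) and 954 (846 to 1073), and Ccr6 at 237 (152 to 353) and 112 (77.4 to 158). It also had the ILC2 marker Gata3 at 316 (216 to 446) and 296 (237 to 366) CPM, Cd4 at 692 (539 to 874) and 181 (135 to 236), and Cd3e at 109 (54.3 to 194) and 106 (71.8 to 149.9). B-like cells of the same libraries held Cd3e at 62.2 (34.0 to 104) and 174 (125 to 237) CPM, intervals that overlap those of cluster 17. Il1r1 stood at 296 (200 to 423) and 198 (150 to 255) CPM in cluster 17. Il22 stood there at 178 (105 to 281) and 30.7 (14.0 to 58.2) CPM, from 2 of 43 and 3 of 103 cells. The genes from Kit to Il22 were picked after the data were seen, and what the cluster is stays open. In the intestine, ILC3-like cells were 88.7% (87.6 to 89.7%) after sham surgery and 83.6% (82.5 to 84.6%) after UUO. Epithelium-like cells followed at 6.0% (5.23 to 6.84%) and 8.98% (8.19 to 9.81%). Cells of the monocyte/macrophage class were 1.40% (1.04 to 1.85%) and 2.83% (2.39 to 3.33%) of the intestinal libraries. Of these, 48 of 49 sham cells and 48 of 140 UUO cells carried a barcode found in both intestinal libraries, so the shares cannot be taken as those of separate cells. How many epithelium-like cells carried such a barcode was not counted. Cells left without a class name were 1.67% and 3.13% in kidney and 1.71% and 2.12% in intestine. A sort set all of these shares, so they describe sorted cells and not the organs.

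Different clusters held the kidney T-like cells of the 2 libraries. Cluster 3, led by Blk, Trgc2, Zbtb16 and Cd40lg, held 41.3% of them in wild-type kidney at day 14 and 8.90% in the knockout-labelled library. Cluster 0, led by Cd8b1, Cd8a, Gzmk and Ccl5, held 15% and 69.1%. A cluster filled mostly by 1 library can stand for that library, so T-like cells were compared by cluster. The ILC3-like cells of the intestine fell into clusters 1, 2 and 5 in near-equal parts of both libraries. The parts were 46.4, 28.8 and 24.8% in sham and 46.9, 28.2 and 24.8% after UUO.

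**Figure D1:**
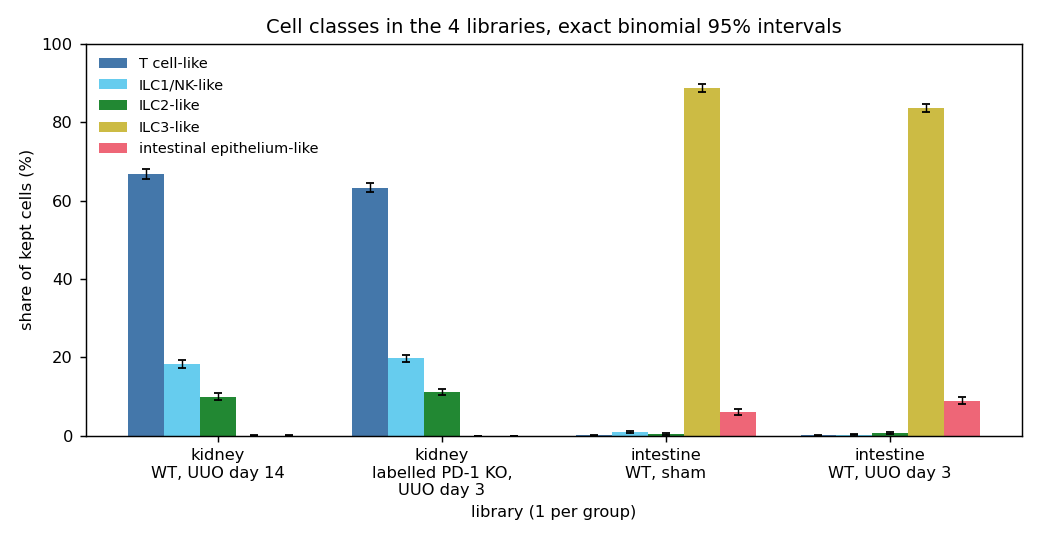
Share of kept cells (%) in 5 cell classes for the 4 libraries, 1 per group. Error bars are exact binomial 95% intervals. T-like cells were 66.8% and 63.3% of the kidney libraries, and ILC3-like cells 88.7% and 83.6% of the intestinal libraries.

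In intestinal ILC3-like cells, the chemokine receptor gene Cxcr6 and the cytokine gene Csf2 were lower 3 days after UUO than after sham surgery. The gut-homing receptor gene Ccr9 was higher. The cytokine gene Il17a was lower in CPM, but its UMIs came from 75 UUO and 76 sham cells, with overlapping shares. Il22, the main cytokine of these cells, was slightly lower. Il23r stood at the same level. The clock genes Per2 and Tef and the glucocorticoid-induced genes Sgk1 and Fkbp5 were higher. The MHC class II genes H2-Eb1 and Cd74 were lower. Enterocyte genes such as Fabp2 and Apoa1 had the highest ratios and goblet cell genes such as Zg16 the lowest. In epithelium-like cells of the same libraries Fabp2, Apoa1 and Zg16 differed in the same direction, but the epithelial marker list stood at 0.05 (percentile 60.5). Over the 9096 genes with at least 100 UMIs, the 5th and 95th percentiles of the log2 ratio were -0.37 and 0.47.

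Among the genes always reported, Cxcr6 (chromosome 9, 123806475 to 123811760, plus strand), the receptor for Cxcl16, was 607 against 889.9 CPM, log2 -0.55 (-0.61 to -0.50). Ccr9 (chromosome 9, 123678439 to 123784330, plus strand), which directs cells to the small intestine, was 174 against 110.2 CPM, log2 0.66 (0.53 to 0.78). That ratio came from cluster 2, where Ccr9 was 445 against 267 CPM, log2 0.74 (0.60 to 0.88). It was 0.22 (-0.31 to 0.76) in cluster 1 and 0.03 (-0.44 to 0.50) in cluster 5. Il17a (chromosome 1, 20730905 to 20734496, plus strand) was 18.4 against 30.2 CPM, log2 -0.71 (-1.01 to -0.41). Its UMIs lay in 75 of 4135 UUO and 76 of 3106 sham cells. These shares, 1.81% (1.43 to 2.27%) and 2.45% (1.93 to 3.05%), have overlapping intervals. Il22 (chromosome 10, 118204942 to 118210047, plus strand) was 4715 against 5180.2 CPM, log2 -0.14 (-0.16 to -0.12). Il23r (chromosome 6, 67422932 to 67491855, minus strand) was 375 against 372 CPM, log2 0.01 (-0.06 to 0.09). Pdcd1 was 64.2 against 59.7 CPM, log2 0.11 (-0.08 to 0.29).

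The highest ratios belonged to genes of absorptive enterocytes. The cytochrome gene Cyp3a11 was 54.3 against 13.5 CPM, log2 2.01 (1.68 to 2.35). The fatty acid binding protein gene Fabp2 was 436 against 109 CPM, log2 2.00 (1.89 to 2.12), and Fabp1 97.0 against 34.1 CPM, log2 1.51 (1.30 to 1.73). The apolipoprotein gene Apoa1 was 403 against 137 CPM, log2 1.56 (1.45 to 1.67). The lectin gene Clec2h (1.60, 1.37 to 1.84), Cyp3a13 (1.47, 1.19 to 1.75), the lipid regulator Creb3l3 (1.46, 1.21 to 1.71) and the brush border peptidase gene Anpep (1.39, 1.27 to 1.51) followed. At the other end, the goblet cell genes Zg16 (40.4 against 156 CPM, log2 -1.95, -2.12 to -1.78), Fcgbp (-0.96, -1.14 to -0.77), Tff3 (-0.95, -1.13 to -0.77) and Muc2 (-0.93, -1.15 to -0.70) were lowest. Genes that lymphoid cells express came next. Ptgs2, the cyclooxygenase-2 gene, was 122 against 214 CPM, log2 -0.82 (-0.93 to -0.70). Csf2, which encodes GM-CSF, was 109 against 187 CPM, log2 -0.78 (-0.90 to -0.66). The antimicrobial gene Reg3g of epithelial cells was also lower (-0.68, -0.84 to -0.53). In epithelium-like cells Fabp2 stood at 7127 CPM after UUO against 2959 in sham and Apoa1 at 5590.4 against 2908.

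The circadian clock list had a median ratio of 0.18 (percentile 99.47) among random lists of like expression. It had 6 of 15 measured members at least 1.5 times higher and 0 at least 1.5 times lower. Per2, a repressor of the clock, was 21.1 against 6.90 CPM, log2 1.61 (1.14 to 2.11), and the clock output gene Tef 46.9 against 24.2 CPM, log2 0.96 (0.69 to 1.23). Further members were Dbp 0.93 (0.12 to 1.8) and Per3 0.72 (0.21 to 1.26). The glucocorticoid response list, with 2 of 11 measured members at least 1.5 times higher and 0 at least 1.5 times lower, stood at 0.19 (percentile 99.91), and over all kept cells at 0.072. Its kinase gene Sgk1 was 47.1 against 26.9 CPM, log2 0.81 (0.56 to 1.07). The receptor cochaperone gene Fkbp5 was 79.1 against 48.3 CPM, log2 0.71 (0.52 to 0.90). Klf9 stood at 0.37 (0.23 to 0.51) and Zbtb16, which encodes PLZF, at 0.37 (0.13 to 0.62). The labels give no time of day for tissue collection. MHC class II genes, which ILC3s use to present antigen, stood at -0.33 (percentile 0.0800), with 0 of 7 measured members at least 1.5 times higher and 1 at least 1.5 times lower. Cd74 was at 399 against 503 CPM, log2 -0.33 (-0.40 to -0.27). H2-Eb1 was at 156 against 202 CPM, log2 -0.37 (-0.48 to -0.26) and H2-DMb1 at -1.01 (-1.84 to -0.19). The MHC class II list was at -0.39 in cluster 1, -0.048 in cluster 2 and 0.16 in cluster 5, and over all kept cells at -0.070. Dendritic cell markers stood at -0.17 (percentile 2.72) in the ILC3-like cells.

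The other lists lay inside the central 95% of random lists, given here as median and percentile. For ILC3 programmes these were ILC3 identity and regulators 0.01 (66), ILC3 cytokines and effectors -0.07 (11.1), LTi/CCR6 subset 0.09 (91.2), NCR+/type 1 ILC3 subset 0.10 (96.4) and migration and homing receptors 0.02 (69.0). Signalling lists stood at PD-1 axis and inhibitory receptors 0.04 (63.5), IL-17 and JAK-STAT signalling 0.01 (60.0), NF-kB and TNF response -0.10 (5.94), TGF-beta response and fibrosis-linked -0.01 (42.6), interferon response 0.02 (62.3) and MHC class I -0.00 (51.9). Stress and survival lists stood at dissociation and immediate early 0.03 (84.2), heat shock 0.07 (92.1) and apoptosis and survival -0.06 (16.2). Growth and metabolism lists stood at cell cycle -0.06 (20.1), glycolysis 0.06 (89.9), oxidative phosphorylation (nuclear) -0.05 (18.9) and lipid metabolism 0.01 (55.4). Single clusters differed from these pooled values. The NCR+/type 1 list was at -0.21 (percentile 0.825) in cluster 1 and 0.21 (percentile 99.95) in cluster 2, and the PD-1 axis list at 0.22 (percentile 96.8), -0.31 (percentile 0.270) and 0.22 (percentile 88.8) in clusters 1, 2 and 5. Outside the central range lay also glycolysis in clusters 1 and 5, at 0.13 (percentile 98.8) and 0.18 (percentile 97.6), and in cluster 5 heat shock at 0.19 (percentile 99.29) and lipid metabolism at 0.29 (percentile 99.50). Of the effector cytokines, Ifng, the type 1 cytokine gene, was 15.8 against 7.50 CPM, log2 1.07 (0.60 to 1.56) and Tnf 0.42 (0.25 to 0.58). Ifng UMIs lay in 1.74% (1.36 to 2.19%) of UUO and 1.09% (0.759 to 1.53%) of sham cells, intervals that overlap. Furin, which encodes a convertase that activates TGF-beta, was 895 against 1217 CPM, log2 -0.44 (-0.49 to -0.40). Ctla4, an inhibitory receptor gene, was 58.9 against 42.8 CPM, log2 0.46 (0.25 to 0.67). Of the homing genes, Itgae, which encodes the CD103 chain that binds epithelial cadherin, was 4.40 against 1.35 CPM, log2 1.70 (0.64 to 2.93). Ccr6, the receptor gene of the LTi subset, was 137 against 118 CPM, log2 0.22 (0.09 to 0.35). The heat shock gene Hspa1a was -1.14 (-1.52 to -0.76). The immediate early genes Egr1 304 against 178 CPM, log2 0.77 (0.67 to 0.87) and Dusp2 -1.43 (-2.03 to -0.84) moved apart.

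Markers of other cell types, counted in the same ILC3-like cells, gave the following medians and percentiles: intestinal epithelium 0.59 (100), mast cell/basophil 0.66 (93.8), ILC2 0.20 (96.0), endothelium 0.16 (70.8), ILC1/NK 0.04 (67.9), monocyte/macrophage 0.03 (53.2), T cell 0.02 (54.9) and ILC3 -0.02 (45.5). Lower medians were those of gamma-delta T cell -0.10 (21.1), dendritic cell -0.17 (2.72), plasma cell -0.45 (0.335), erythroid -0.64 (0.160) and fibroblast/pericyte -0.81 (0.0200). B cell, neutrophil, kidney epithelium and glia/neuron markers had fewer than 3 measured members. The day of sham tissue collection is not given in the labels. With 1 library on each side, a difference between mice or between library preparations would look the same as an effect of the obstruction.

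**Figure D2:**
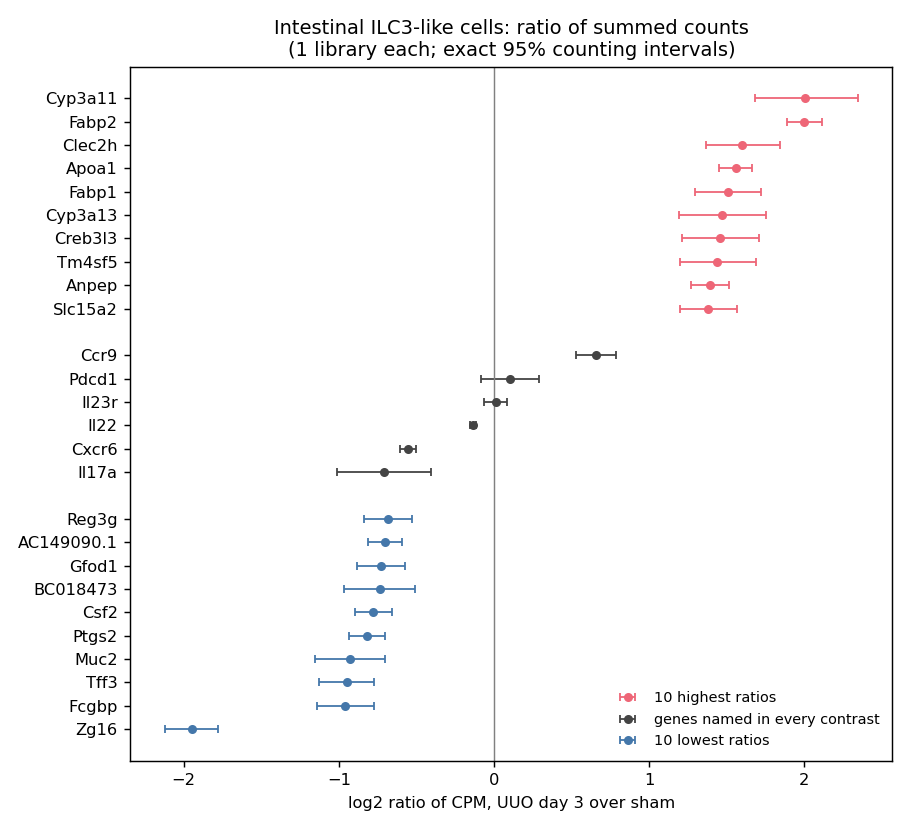
Log2 ratio of CPM (x axis; UUO day 3 over sham) in intestinal ILC3-like cells for the 10 highest and 10 lowest genes and the genes reported in every comparison (y axis). Error bars are exact 95% counting intervals, 1 library per group. Cyp3a11 was highest at 2.01, Zg16 lowest at -1.95, with Ccr9 at 0.66 and Cxcr6 at -0.55.

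In kidney ILC2-like cells, the library labelled PD-1 knockout (day 3) had higher levels of the cell cycle genes Mcm5 and Stmn1, the glycolysis genes Pkm and Slc2a1 and the MHC class II genes H2-Eb1 and H2-Aa than wild-type kidney at day 14. The GM-CSF gene Csf2 was higher. The stress genes Hspa1a and Hspa1b, the glucocorticoid-induced gene Tsc22d3 and the receptor gene Kit were lower. Cytotoxic and T cell genes such as Nkg7, Gzma, Cd8b1 and Cd3e were also higher, side by side with markers of T, ILC1/NK and kidney epithelial cells. B-like cells of the 2 libraries, a measure of background, held Cd3e at 174 (125 to 237) against 62.2 (34.0 to 104) CPM. Their Cd8b1 was 55.3 (29.5 to 94.6) against 4.44 (0.113 to 24.8) CPM. In ILC2-like cells neither Cd3e nor Cd8b1 stood above these levels in either library. Pdcd1 differed little. Genotype and day after surgery differ together between these 2 libraries and cannot be told apart.

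Pdcd1 was 147 against 157 CPM, log2 -0.10 (-0.35 to 0.16) in the 776 knockout-labelled and 519 wild-type ILC2-like cells. Their medians were 2926 and 2332 UMIs per cell. Cxcr6 was 486 against 424 CPM, log2 0.19 (0.05 to 0.35). Ccr9 was 175 against 252 CPM, log2 -0.52 (-0.74 to -0.31). Over all kept cells these ratios turned to -0.68 and 0.053. Il17a, Il22 and Il23r, which ILC2s are not known for, stood below 10 CPM in both libraries. The highest ratio was that of Spp1, the osteopontin gene, at 54.2 against 3.98 CPM, log2 3.77 (2.51 to 5.42). Clu, an injury gene of kidney tubules, followed at 62.5 against 11.1 CPM, log2 2.49 (1.70 to 3.39). Spp1 and Clu are among the leading genes of kidney epithelium-like cluster 25. Next came Ly6c2 (2.29, 1.64 to 3.02), the cytotoxic granule gene Nkg7 (151 against 38.2 CPM, log2 1.98, 1.54 to 2.45) and Stmn1 (1.89, 1.31 to 2.51). The costimulator gene Cd28 (1.55, 0.93 to 2.23) and Cd3e (146 against 52.5 CPM, log2 1.47, 1.09 to 1.87) came after these. The lowest were the heat shock genes Hspa1a (6.21 against 131 CPM, log2 -4.39, -5.26 to -3.63) and Hspa1b (-3.25, -3.66 to -2.85). Further low ratios were those of Gda (-1.89, -2.33 to -1.46), Ttn (-1.75, -2.20 to -1.30), Igfbp4 (-1.63, -1.98 to -1.28) and Tsc22d3, which encodes GILZ (164 against 386 CPM, log2 -1.24, -1.43 to -1.04). The cytokine genes Lif (-1.17, -1.46 to -0.88) and Il2 (-1.13, -1.66 to -0.60) were also near that end. Over all kept cells Cd3e and Ttn turned to -0.26 and 0.28.

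The cycling cells of cluster 18 are not part of this class. The cell cycle list had a median of 0.81 (percentile 100), with 6 of 9 measured members at least 1.5 times higher and 0 at least 1.5 times lower. Its replication genes Mcm5 and Mcm6 were 1.41 (0.96 to 1.89) and 1.07 (0.68 to 1.48) and Top2a 0.85 (0.34 to 1.40). Glycolysis stood at 0.39 (percentile 99.98), with 4 of 16 measured members at least 1.5 times higher and 0 at least 1.5 times lower. Pkm was at 347 against 226 CPM, log2 0.62 (0.42 to 0.82) and the glucose transporter gene Slc2a1 at 0.82 (0.29 to 1.39). Lipid metabolism stood at 0.33 (percentile 99) with the sterol regulator Insig1 at 0.98 (0.33 to 1.68), and oxidative phosphorylation at 0.17 (percentile 98.6). Oxidative phosphorylation came to lie inside the central range at 0.15 with resolution 2.0, 0.11 with thinned cells and 0.16 without the highest doublet scores, and over all kept cells it was -0.036. Lipid metabolism did so at 0.21 with a lower minimum for members, 0.30 without cells that hold a CD3 UMI and 0.097 over all kept cells, where glycolysis was 0.037. MHC class II was at 0.54 (percentile 100), with 2 of 5 measured members at least 1.5 times higher and 0 at least 1.5 times lower. H2-Eb1 was at 383 against 210.1 CPM, log2 0.87 (0.67 to 1.07) and H2-Aa at 467 against 279 CPM, log2 0.75 (0.57 to 0.92). The NCR+/type 1 ILC3 list, which holds the type 1 regulator Tbx21 (2.28, 0.58 to 4.64) and the granzyme gene Gzma (2.14, 0.92 to 3.66), stood at 1.0 (percentile 100), and over all kept cells at 0.084. Interferon response stood at 0.29 (percentile 98.7), with Ifi27l2a at 1.5 (0.46 to 2.71), and at 0.038 without cells that hold a CD3 UMI. Lower lists were LTi/CCR6 subset at -0.67 (percentile 0.0550), with Nrp1 at -0.87 (-1.28 to -0.46), and ILC3 identity and regulators at -0.26 (percentile 0.220). Kit was at 246 against 454 CPM, log2 -0.88 (-1.05 to -0.72) and Maf at -0.68 (-0.90 to -0.45). The ILC3 identity list came to lie inside the central range at -0.10 with resolution 2.0, -0.13 without cells that hold a CD3 UMI, -0.15 with any barcode and -0.16 with thinned cells. Dissociation and immediate early genes stood at -0.24 (percentile 0.060), with Fosb at -0.51 (-0.57 to -0.45), and over all kept cells at 0.00087.

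Inside the central range of random lists lay PD-1 axis and inhibitory receptors -0.13 (13.8), ILC3 cytokines and effectors -0.13 (10.3), migration and homing receptors 0.07 (82.6), IL-17 and JAK-STAT signalling 0.14 (88.8), NF-kB and TNF response 0.15 (96.5), heat shock 0.00 (54.6) and MHC class I 0.10 (85.6). So did circadian clock 0.16 (81.3), apoptosis and survival -0.10 (12.1), glucocorticoid response -0.17 (3.63) and TGF-beta response and fibrosis-linked -0.01 (43.1). Of their members, Csf2 was 210.3 against 106 CPM, log2 0.99 (0.71 to 1.28). The chemokine receptor gene Ccr2 was 497 against 837 CPM, log2 -0.75 (-0.87 to -0.63). The fibroblast-linked genes S100a4 and Pdgfa were 549 against 238 CPM, log2 1.20 (1.02 to 1.39) and -2.10 (-3.17 to -1.11). The clock gene Nr1d1 was 1.43 (0.69 to 2.24). Markers of other cell types were higher in the knockout-labelled ILC2-like cells: T cell 0.61 (100), ILC1/NK 1.25 (100), kidney epithelium 1.89 (99.91), monocyte/macrophage 2.29 (100), plasma cell 3.40 (99.97) and erythroid 2.38 (100). Gamma-delta T cell and dendritic cell markers lay inside the central range, at gamma-delta T cell 0.33 (95.7) and dendritic cell 0.28 (94.2). ILC2 and ILC3 markers stood at ILC2 -0.15 (4.22) and ILC3 -0.29 (1.27). Of the knockout-labelled and wild-type ILC2-like cells, 42.3% (17.8%, 15.1 to 20.7%) and 17.3% (8.48%, 6.21 to 11.3%) held a CD3 UMI, thinned shares in brackets, with 34 and 12 cells left out.

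In kidney ILC1/NK-like cells, Pdcd1 itself had the highest ratio, higher in the library labelled PD-1 knockout (day 3) than in wild-type kidney at day 14. The chemokine gene Ccl1, the growth factor gene Mdk, the MHC class II genes H2-Eb1, H2-Aa and Cd74, and the NF-kB targets Cd83, Nfkbie and Nfkb2 were higher as well. Ifng, the signature cytokine of these cells, the Ly49 receptor genes Klra9 and Klra1 and the integrin gene Itga1 were lower. The make-up of the class differed, since cluster 9, which has Ly49 genes among its leading genes, held 26.1% of the wild-type and 19.7% of the knockout-labelled cells. T cell and kidney epithelial markers such as Cd8b1 and Fxyd2 were also higher. In B-like cells of the same libraries Cd8b1 was 55.3 (29.5 to 94.6) against 4.44 (0.113 to 24.8) CPM, near its levels in the ILC1/NK-like cells. Spp1 and Clu, higher as well, are among the leading genes of kidney epithelium-like cluster 25. As in ILC2-like cells, genotype and day differ together.

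Pdcd1 was 159.7 against 16.5 CPM, log2 3.28 (2.75 to 3.86) in the 1377 knockout-labelled and 951 wild-type cells. Their medians were 2234 and 1827 UMIs per cell. The share of cells with a Pdcd1 UMI was 25.5% (13.1%, 11.4 to 15.1%) against 2.31% (1.23%, 0.614 to 2.19%), with 45 and 55 cells left out by thinning. By cluster, cluster 4, led by Xcl1, Klrb1c and Ncr1, held 187 (170.4 to 204) against 18.0 (11.5 to 26.8) CPM. Cluster 9, led by Klra8, Gzma and Eomes, held 48.9 (33.2 to 69.4) against 12.3 (4.50 to 26.7). B-like cells of the same libraries, a measure of background, held 29.8 (12.0 to 61.4) and 22.2 (7.21 to 51.8) CPM. Among T-like cells, Pdcd1 was 299.9 (286 to 315) against 151 (126 to 179.8) CPM in cluster 0. It was 110.0 (90.6 to 132) against 217 (199.8 to 234) in cluster 3 and 146 (124 to 172) against 62.7 (49.7 to 78.0) in cluster 7.

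**Figure D3:**
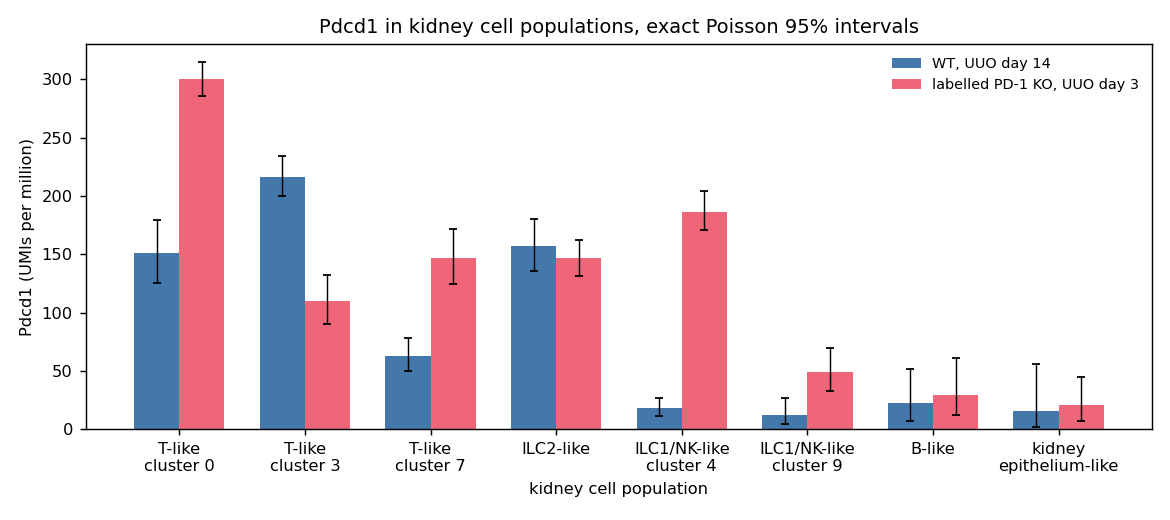
Pdcd1 level (CPM, y axis) in kidney cell populations of wild-type kidney at day 14 and of the library labelled PD-1 knockout at day 3, 1 library each. Error bars are exact Poisson 95% intervals. In ILC1/NK-like cluster 4 the levels were 18.0 and 187, and in ILC2-like cells 157 and 147.

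After Pdcd1 the highest ratios were those of Spp1 (57.4 against 7.14 CPM, log2 3.01, 2.20 to 3.94), Cd8b1 (52.4 against 7.14 CPM, log2 2.88, 2.06 to 3.82) and Clu (2.78, 2.02 to 3.65). Then came Mdk, which encodes midkine (90.7 against 13.2 CPM, log2 2.78, 2.18 to 3.45), and Ccl1, a ligand of Ccr8 (225 against 38.4 CPM, log2 2.55, 2.19 to 2.92). Of the MHC class II genes, the highest were H2-Eb1 (579 against 143 CPM, log2 2.02, 1.83 to 2.21), H2-Aa (1.86, 1.71 to 2.01) and the invariant chain gene Cd74 (1303 against 361 CPM, log2 1.85, 1.73 to 1.97). The lowest were Hspa1b (4.63 against 102 CPM, log2 -4.46, -5.33 to -3.71), Klra9 (92.2 against 236 CPM, log2 -1.35, -1.57 to -1.14) and Klra1 (-1.29, -1.68 to -0.91). They were followed by Ifng (34.2 against 82.9 CPM, log2 -1.28, -1.64 to -0.91), the kinase gene Styk1 (-1.27, -1.64 to -0.91) and Rin3 (-1.26, -1.65 to -0.87). Over all kept cells the Ifng ratio turned to 0.14. Cxcr6 was 117 against 138 CPM, log2 -0.23 (-0.46 to 0.01), and Il17a 0.925 against 9.33 CPM, log2 -3.33 (-5.75 to -1.55). Ccr9, Il22 and Il23r stood below 10 CPM in both libraries.

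MHC class II had the highest median of the lists, 1.55 (percentile 100), with 5 of 7 measured members at least 1.5 times higher and 1 at least 1.5 times lower. NF-kB and TNF response stood at 0.52 (percentile 100), led by the activation marker Cd83 (249 against 78.5 CPM, log2 1.66, 1.41 to 1.93), Nfkbie (0.93, 0.72 to 1.14) and Nfkb2 (0.90, 0.65 to 1.15). ILC3 identity and regulators stood at 0.29 (percentile 99.93), with Tmem176b at 689.6 against 400.3 CPM, log2 0.78 (0.66 to 0.91). Heat shock stood at 0.23 (percentile 99.34), with Hspa1a at -6.31 (-9.38 to -4.41) and Hsph1 at 0.66 (0.41 to 0.93) moving apart. PD-1 axis and inhibitory receptors stood at 0.20 (percentile 98.6), with Tigit at 94.1 against 143 CPM, log2 -0.60 (-0.85 to -0.36). In cluster 9 alone these 5 lists stood at 0.16, 0.0069, -0.010, -0.039 and -0.0090 in the same order. MHC class II and NF-kB were not particular to ILC1/NK-like cells. In T-like clusters 0, 3 and 7, MHC class II stood at 2.00, 1.59 and 1.66. NF-kB and TNF response stood there at 0.41, 0.16 and 0.52, each above the central range. With members of at least 100 UMIs the PD-1 axis list was at -0.0033, and with thinned cells at 0.017. Over all kept cells ILC3 identity and regulators turned to -0.27. Lists inside the central range were ILC3 cytokines and effectors -0.02 (55.9), LTi/CCR6 subset 0.09 (77.9), NCR+/type 1 ILC3 subset -0.19 (2.79), migration and homing receptors -0.15 (5.19), IL-17 and JAK-STAT signalling 0.15 (96.2), dissociation and immediate early 0.10 (94.0), interferon response 0.17 (97.3) and MHC class I 0.08 (88.3). So were cell cycle 0.21 (97.3), glycolysis 0.08 (91.5), oxidative phosphorylation (nuclear) -0.00 (73.7), lipid metabolism 0.15 (92.4), circadian clock 0.05 (76.5), apoptosis and survival -0.04 (55.5), glucocorticoid response 0.01 (68.3) and TGF-beta response and fibrosis-linked 0.10 (94.9). Among their members, Itga1, the CD49a chain of tissue-resident cells, was 84.8 against 183 CPM, log2 -1.11 (-1.34 to -0.87). Csf2 was 2.75 (1.09 to 5.10), the death receptor gene Fas 1.39 (0.72 to 2.13), Ly6a 1.24 (0.90 to 1.58) and Isg15 -1.02 (-1.69 to -0.34).

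Markers of other cell types counted in these ILC1/NK-like cells stood at T cell 0.80 (100), kidney epithelium 4.14 (100), erythroid 3.34 (99.995), plasma cell 1.06 (99.30), monocyte/macrophage 0.76 (99.85), dendritic cell 0.36 (99.61), ILC2 0.39 (99.75), ILC3 0.22 (96.8) and gamma-delta T cell -0.30 (5.12). The tubule gene Fxyd2 was 19.4 against 1.10 CPM, log2 4.14 (2.23 to 7.22). Their own ILC1/NK markers stood at -0.37 (percentile 0), with the receptor gene Klre1 at 315 against 633 CPM, log2 -1.0 (-1.13 to -0.88). A CD3 UMI was found in 34.2% (18.2%, 16.2 to 20.4%) of the knockout-labelled and 15% (8.48%, 6.74 to 10.5%) of the wild-type ILC1/NK-like cells, thinned shares in brackets.

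Il22 was far higher in sorted intestinal cells than in sorted kidney cells, and Cd3e was far lower. Ccr9, Il23r, Kit and Ccr6 were higher in both intestinal libraries than in both kidney libraries. Il17a was highest in wild-type kidney, and Cxcr6 there stood above its level in UUO intestine. Cells named ILC3-like were too few in kidney, 2 and 0 without the unnamed cluster 17, for any contrast of ILC3-like cells with the intestine or between the kidney libraries. Tissue and sort differ together here, along with genotype for the knockout-labelled kidney and day for wild-type kidney, so values are given side by side over all kept cells.

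In the order UUO intestine, sham intestine, knockout-labelled kidney and wild-type kidney, Il22 stood at 3374 (3343 to 3405), 4366 (4321 to 4411), 0.616 (0.296 to 1.13) and 14.0 (11.8 to 16.5) CPM. Il23r, the receptor gene for interleukin 23, was at 264 (256 to 273), 306 (295 to 319), 11.8 (10.2 to 13.6) and 48.2 (44.1 to 52.7) CPM. Il17a was at 13.2 (11.3 to 15.2), 24.4 (21.2 to 28.0), 12.4 (10.7 to 14.2) and 98.8 (92.8 to 105) CPM. Cxcr6 was at 436 (425 to 447), 747 (728 to 766), 284 (276 to 292) and 455 (442 to 469) CPM. Ccr9 stood at 131 (125 to 137), 98.1 (91.5 to 105), 53.7 (50.2 to 57.4) and 51.8 (47.5 to 56.4) CPM. The stem cell factor receptor gene Kit stood at 1045 (1028 to 1062), 1201 (1178 to 1225), 102 (97.0 to 107) and 108 (101 to 114) CPM. Ccr6 was at 94.2 (89.1 to 99.4), 96.1 (89.5 to 103), 19.6 (17.5 to 21.9) and 64.4 (59.6 to 69.5) CPM. The interleukin 1 receptor gene Il1r1 was at 446 (435 to 457), 612 (595 to 629), 26.6 (24.2 to 29.3) and 107 (101 to 114) CPM. Cd3e, of the T cell receptor complex, was at 27.2 (24.6 to 30.1), 20.8 (17.8 to 24.2), 655 (643 to 668) and 784 (767 to 802) CPM. The kinase gene Blk was at 42.1 (38.7 to 45.6), 57.7 (52.6 to 63.1), 53.1 (49.6 to 56.8) and 166 (158 to 174) CPM. Il17a was higher in wild-type kidney at day 14 than in the knockout-labelled kidney.

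Within T-like cluster 3 of the kidney, wild-type and knockout-labelled cells had Il23r at 150.4 (136 to 165) and 149 (127 to 175) CPM. The delta chain gene Trdc was at 222 (205 to 239.6) and 419 (379.7 to 460.2), while the gamma-delta T cell markers as a list were lower in the knockout-labelled cells, at -0.56 (percentile 0), with 2 of 7 measured members at least 1.5 times higher and 2 at least 1.5 times lower. Il17a was at 218 (201 to 236) and 99.2 (80.8 to 121) CPM in these T-like cells.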

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

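The tests of shared barcodes were chosen after the result was seen. The intestinal sham and UUO libraries had 158 barcodes in common (134 to 185), drawn to attention because barcodes outside the main measurement gave a signal above the level that chance allows. From the 2 library sizes and 884736 possible barcodes, 21.3 shared barcodes were expected by chance, with an upper limit of 31. The other 5 pairs of libraries with barcodes shared 22 to 27, against 21.6 to 32.5 expected.

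Chance reuse of barcodes was argued against by the 158 shared barcodes themselves, which lie above the upper limit of 31. Transfer of barcoded molecules was tested by the likeness of the 154 pairs of kept cells: their median correlation was 0.427, above all 100 draws of random pairs from the same clusters (0.318 to 0.366). Of these pairs, 85 lay in the same cluster in both libraries and 48 in cluster 14, led by the macrophage genes Chil3, Lyz2, Lpl, Mrc1 and Ear1, where 48 of 49 sham cells had a shared barcode. The macrophage-like cells of the sham library are therefore likely to include transferred molecules. Transfer between this pair and transfer from some other library into both would give the same values. The other shared pairs lay outside cluster 14, and their classes were not counted, so epithelium-like cells may be affected too. Chil3 had a UMI in 39.0% of sham and 34.9% of UUO ILC3-like cells, so macrophage transcripts were not confined to cluster 14. No biological explanation was tested, and without the shared barcodes ILC3-like cells were 92.3% of sham and 86.0% of UUO cells in place of 88.7 and 83.6%.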

How the results depend on the processing

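The settings for doublet scores, CD3, single clusters and shared barcodes were chosen after the data were seen, and the others before. No paired analysis was possible because each group is 1 library and the labels link no mice across libraries. Of the values that answer a comparison, 343 stayed within their interval or on their side of the central range of random lists. Another 69 moved beyond their interval, 28 lists came to lie inside that range and 8 lists changed sign. Counts of lists, named genes and kidney ILC3-like cells have no interval and were called moved beyond a 1.5-fold change. A gene whose interval held 0 was called moved even where its sign changed, as for Pdcd1 in ILC2-like cells over all kept cells. Of the values of single genes and other lists, 1286 stayed, 116 moved, 52 lists came to lie outside the range and 5 genes changed sign. The 116 include 7 lists that came to lie outside the range with a changed sign. For each change the cause was not tested unless a reason is given. In the following, values under a setting come with the reported value in brackets.

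With any barcode of at least 1 UMI, the kept cells were 7007, 5282, 3621 and 5209 in knockout-labelled kidney, wild-type kidney, sham and UUO intestine (6960, 5212, 3501 and 4946), by construction. Knockout-labelled T-like cells were 60.9% (63.3) and ILC2-like cells 12.1% (11.1), wild-type T-like cells 60.9% (66.8) and wild-type kidney ILC3-like cells 4 (2). ILC3-like cells were 85.9% (88.7) in sham and 79.8% (83.6) after UUO, Il22 4209 CPM (4366) in sham and 3223 (3374) after UUO, and ILC3 identity in ILC2-like cells -0.15 (-0.26). With the strict filter of 1000 UMIs, the kept cells were 6475, 4825, 3203 and 4270 and median UMIs 2118 (2064.5), 1871 (1824), 2111 (2039) and 2281.5 (2177), by construction. T-like cells were 58.0% (63.3) and 58.5% (66.8) in knockout-labelled and wild-type kidney, wild-type kidney ILC3-like cells 1 (2), and ILC3-like cells 93.4% in sham and 89.8% after UUO. Il22 was 4478 CPM in sham and 3544 after UUO, and the PD-1 axis list in ILC1/NK-like cells 0.16 (0.20).

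At resolution 0.5, the knockout-labelled library had 12.2% ILC2-like and 20.8% ILC1/NK-like cells (11.1 and 19.8), and wild-type kidney 65.3% T-like and 19.7% ILC1/NK-like cells (66.8 and 18.2). The interferon list in ILC2-like cells was 0.25 (0.29), and 9 lists lay outside the range in ILC1/NK-like cells (5). At resolution 2.0, T-like cells were 61.4% in the knockout-labelled library and 61.2% in wild-type kidney, and knockout-labelled ILC2-like cells 12.4%. In ILC2-like cells ILC3 identity was then -0.10 (-0.26) and oxidative phosphorylation 0.15 (0.17). With each library clustered alone, clusters were still named against all other cells of the 4 libraries. The marker bar was therefore unchanged, and this setting cannot tell its effect from that of the clustering. Knockout-labelled ILC2-like cells were then 12.2%, wild-type T-like cells 60.1% and ILC1/NK-like cells 24.3%. Wild-type kidney ILC3-like cells were 0, and intestinal ILC3-like cells 66.8% in sham and 57.2% after UUO.

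Over all kept cells, which hold other cell types by construction, Pdcd1 was 50.5 CPM in sham (59.7) and 46.9 after UUO (64.2). The intestinal ratio of Cxcr6 was -0.78 (-0.55), of Ccr9 0.41 (0.66), of MHC class II -0.070 (-0.33) and of glucocorticoid response 0.072 (0.19), with 7 lists outside the range (3). Against the ILC2-like ratios, Cd3e turned to -0.26 (1.47), Ttn to 0.28 (-1.75), Cxcr6 to -0.68 (0.19), Ccr9 to 0.053 (-0.52), dissociation to 0.00087 (-0.24) and oxidative phosphorylation to -0.036 (0.17). Pdcd1 was 0.58 (-0.10), the NCR+ list 0.084 (1.0), interferon 0.11 (0.29), glycolysis 0.037 (0.39) and lipid metabolism 0.097 (0.33). Against the ILC1/NK-like ratios, Ifng turned to 0.14 (-1.28) and ILC3 identity to -0.27 (0.29), Pdcd1 was 0.58 (3.28), and 11 lists lay outside the range (5).

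With totals without mitochondrial and ribosomal genes, which are smaller by construction, Il22 was 16.6 CPM in wild-type kidney (14.0), 4875 in sham and 3780.3 after UUO. With TMM factors Il22 in sham was 4236 CPM. With cells thinned to 1000 UMIs, Il22 was 4893 and 4084 CPM in sham and UUO intestine. There 5 intestinal lists lay outside the range (3), and ILC3 identity was -0.16 (-0.26), interferon 0.31 (0.29) and oxidative phosphorylation 0.11 (0.17) in ILC2-like cells and PD-1 axis 0.017 (0.20) in ILC1/NK-like cells. With list members of at least 1 UMI in each library, interferon was 0.12 and lipid metabolism 0.21 (0.33) in ILC2-like cells and ILC3 identity 0.13 (0.29) in ILC1/NK-like cells. With at least 100 UMIs, PD-1 axis in ILC1/NK-like cells turned to -0.0033 (0.20).

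Without the cells of highest doublet score, wild-type kidney ILC3-like cells were 0, Il22 4171 CPM in sham and 3246 after UUO, and in ILC2-like cells interferon 0.10 and oxidative phosphorylation 0.16. Scrublet's own calls could not be used as planned, because they marked 7 cells. Without cells with a CD3 UMI, ILC3 identity was -0.13, interferon 0.038 and lipid metabolism 0.30 in ILC2-like cells and PD-1 axis 0.17 in ILC1/NK-like cells. Without shared barcodes, ILC3-like cells were 92.3% in sham and 86.0% after UUO.

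In cluster 1 alone Cxcr6 was -0.63, Ccr9 0.22 and 5 lists lay outside the range, and in cluster 2 alone Cxcr6 was -0.50 and MHC class II -0.048. In cluster 5 alone Ccr9 was 0.028, MHC class II turned to 0.16 (-0.33) and 5 lists lay outside the range. In cluster 4 alone PD-1 axis was 0.15. In cluster 9 alone Pdcd1 was 2.00 (3.28), PD-1 axis turned to -0.0090 (0.20), ILC3 identity to -0.010 (0.29) and heat shock to -0.039 (0.23), NF-kB was 0.0069 (0.52), MHC class II 0.16 (1.55), and 1 list lay outside the range (5).

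Depth limits genes of low count: in simulated data changes of 1.5-fold were placed on the right side of 0 in 82.1 to 95.5% of genes with at least 100 UMIs, and Il17a, Il22 and Il23r in kidney ILC2-like cells lay below that count. Contrasts of kidney ILC3-like cells could not be run under any of these settings, as wild-type kidney held at most 4 cells of that name. All of these settings kept the same marker bar. Cluster 17, with 43 wild-type and 103 knockout-labelled kidney cells, got no name at the marker bar. It held ILC3 genes such as Kit and Ccr6 beside the ILC2 marker Gata3, and Cd3e with intervals that overlap those of B-like cells.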

Other observations

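The comparisons of T-like clusters, epithelium-like cells and single ILC3-like clusters were chosen after the data were seen, and so were the tests of free RNA, of expression by ILC3-like cells and of genotype against day. The tests of doublets and of CD3 were also added once the data had been seen, but what they would show was written down before their own values were. In kidney T-like cluster 3, which carries Il23r, the knockout-labelled library had lower Ctla4 (105 against 354 CPM, log2 -1.75, -2.05 to -1.46), Il17a (-1.14, -1.46 to -0.83) and Egr1 (-2.05, -2.45 to -1.66) and higher Ccl5 (1.42, 1.17 to 1.67) and Gzmb (1.47, 1.05 to 1.90) than wild-type kidney at day 14, and Pdcd1 was lower (110.0 against 217 CPM, log2 -0.98, -1.28 to -0.68). The clock list stood at 0.57 (percentile 100) with Nr1d1 at 78.6 against 33.6 CPM, log2 1.23 (0.78 to 1.67), and MHC class II at 1.59 (percentile 100). Markers of other cell types were higher in the same cells: ILC1/NK 0.75 (percentile 100), monocyte/macrophage 1.66 (percentile 99.99), dendritic cell 0.57 (percentile 99.93) and erythroid 9.67 (percentile 100). Gamma-delta T cell markers were lower, at -0.56 (percentile 0). Haemoglobin UMIs numbered 4612 in its knockout-labelled cells, 33.9% of them in a single cell. In the Cd8b1-led cluster 0, Pdcd1 was higher in the knockout-labelled library (299.9 against 151 CPM, log2 0.99, 0.73 to 1.26), and the residency genes Itga1 (66.3 against 351 CPM, log2 -2.41, -2.63 to -2.18) and Itgae (-2.13, -2.66 to -1.60) were lower, with MHC class II at 2.00 (percentile 100). Other markers were higher as well: ILC3 0.49 (percentile 99.27), ILC2 0.82 (percentile 99.48), kidney epithelium 2.49 (percentile 100) and erythroid 3.73 (percentile 100). Lower were ILC1/NK -0.32 (percentile 0.300) and T cell -0.21 (percentile 1.85). In the Cd4-led cluster 7, the type 17 genes Il17a (52.3 against 266 CPM, log2 -2.35, -2.79 to -1.93) and Il1r1 (-2.53, -3.35 to -1.79) were lower, and Ly6c2 (239.7 against 27.4 CPM, log2 3.13, 2.61 to 3.68), Nkg7 (1.99, 1.68 to 2.31) and Pdcd1 (146 against 62.7 CPM, log2 1.23, 0.83 to 1.63) higher. Here too other markers were higher: ILC1/NK 1.17 (percentile 100), ILC2 0.69 (percentile 100), monocyte/macrophage 2.31 (percentile 100), dendritic cell 0.52 (percentile 99.77) and erythroid 4.14 (percentile 100). ILC3 markers were lower, at -0.72 (percentile 0), with 1 of 14 measured members at least 1.5 times higher and 8 at least 1.5 times lower. In clusters 0 and 7 the clock list stood at 0.37 (percentile 99.1) and -0.11 (percentile 36.2). Whether these T-like cells changed or transcripts of other cells were counted with them was not tested.

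In intestinal epithelium-like cells, the gluconeogenesis gene Pck1 was higher after UUO than after sham surgery (997 against 233 CPM, log2 2.10, 1.92 to 2.28), as were Sult6b2 (2.99, 2.43 to 3.60), the lipid carrier gene Apoa4 (285 against 70.4 CPM, log2 2.02, 1.69 to 2.35) and the clock output gene Tef (60.0 against 15.1 CPM, log2 1.99, 1.30 to 2.77). The goblet cell genes Zg16 (586 against 4505 CPM, log2 -2.94, -3.02 to -2.87) and Clca1 (-2.91, -3.05 to -2.76), the enteroendocrine gene Chga (22.9 against 332 CPM, log2 -3.86, -4.22 to -3.51) and the tryptophan-degrading enzyme gene Ido1 (-3.10, -3.61 to -2.62) were lower. The clusters within this class were filled unequally: enterocyte cluster 16 held 25 sham and 123 UUO cells, and goblet cluster 15 held 77 and 96. The clock list stood at 0.42 (percentile 99.83) and the cell cycle list at -0.71 (percentile 0). Lower as well were ILC3 cytokines and effectors at -0.59 (percentile 0.0300), migration and homing receptors at -0.54 (percentile 0), NF-kB and TNF response at -0.40 (percentile 0.140) and ILC3 identity and regulators at -0.28 (percentile 2.01). Markers of lymphoid cells in these epithelium-like cells were lower too: ILC3 -0.36 (percentile 0.880), ILC1/NK -0.70 (percentile 0.320) and T cell -0.63 (percentile 1.08). In ILC3-like clusters 1, 2 and 5 the clock list stood at 0.36, 0.22 and 0.21 and the glucocorticoid response list at 0.16, 0.19 and 0.33, each above the central range of random lists.

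The first pattern weighed is that enterocyte transcripts such as Fabp2 and Apoa1 were higher and goblet cell transcripts such as Zg16 lower in intestinal ILC3-like cells after UUO. Expression by the ILC3-like cells is argued against, since 0 of the 13 measured epithelial markers stood above their level in cells that were neither ILC3-like nor epithelial in the UUO library. For doublets of ILC3-like and epithelial cells, the median ratio of these markers was 0.62 without the cells of highest doublet score and 0.59 with them. Scrublet's own threshold called 1 sham and 0 UUO cells. Of the cells removed by score, 199 of 210 in sham and 271 of 297 after UUO were ILC3-like. The score may thus not have marked such doublets, and these values cannot decide whether they play a part. Free epithelial RNA stays a candidate explanation: the median absolute log2 ratio between ILC3-like and other non-epithelial cells was 0.121, and epithelium-like cells, which sorting for ILC3s should remove, gave 14.4% of the UMIs in sham and 26.5% after UUO. Whether the epithelium itself changed or other parts of it entered the 2 libraries stays untested.

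The second pattern is the higher Pdcd1 in kidney ILC1/NK-like cells of the library labelled PD-1 knockout. Free RNA from T cells is argued against for cluster 4, since Pdcd1 there was 6.27 times (3.02 to 15.7) its level in B-like cells of the library, which take up the same free RNA. It is not argued against for cluster 9, where Pdcd1 was 48.9 (33.2 to 69.4) CPM, against 29.8 (12.0 to 61.4) in B-like cells. T cells or T cell doublets that hold a CD3 UMI are argued against as the source, since the log2 ratio was 3.52 (2.90 to 4.21) in cells without a CD3 UMI. That filter does not take out all T cell RNA, as Cd8b1 in the remaining cells was still 38.2 (30.2 to 47.8) against 2.00 (0.412 to 5.84) CPM. Genotype and day after surgery cannot be told apart, because 0 days had counts of both genotypes among the libraries compared. Counts of wild-type kidney at day 3 were not used. The transcript level says nothing about PD-1 protein, and a deletion that leaves the 3' tag might also alter transcript abundance, which was not tested.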
